A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

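RNA from 48 samples of 1 culture was labelled with biotin and hybridised to Affymetrix Yeast 2.0 arrays, which carry probe sets for Saccharomyces cerevisiae and for the fission yeast Schizosaccharomyces pombe. The deposited values are linear signal intensities for 10928 probe sets, made with GCOS, per the submitters' processing notes, which give no version. The algorithm, its target value and any later rescaling are not given in the sources used here, so the scale and centring of the columns stay unknown. The median intensity of all probe sets ran from 32.4 to 86.8 between columns, and the 2% trimmed mean from 701 to 1214, while spiked hybridisation controls had a mean log2 of 10.30 ± 0.09 (SD, n = 48). Genes were named through the platform annotation and the R64 gene table, which was used for names only. Of the probe sets 5498 had a Saccharomyces cerevisiae gene, 1747 a fission yeast gene, 1 of these with several symbols and unused for names, and 3683 were unnamed here, including 166 spiked or control probe sets.

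Groups, tests, the rule for named genes, the gene lists and most other settings tried were fixed before the data were examined. That plan called for quantile normalization where trimmed means differed by more than 5%, as they did, so log2 values, with signals under 1 set to 1, were quantile normalized in limma. Probe sets were tested where their mean was above the 90th percentile of the fission yeast probe sets, a background the culture cannot supply. This left 5372 probe sets for 5332 genes, and 126 were left out as dim. For a gene with several probe sets the one of highest mean was named.

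Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) and a Benjamini-Hochberg adjusted p under 0.05. The level comparison set 37 phenelzine against 11 control arrays. The first 40 min comparison paired 10 arrays with those 40 min earlier. Array k of the control lies 44 min before array k after addition, near the cycle length, and deviations from the group means correlated at 0.51 to 0.79 in these 11 pairs, so the level comparison was also fitted with the pair as a block. In that fit only these 11 pairs inform the difference, since later arrays have no partner. Rhythms were F tests of cosine and sine terms, the 80-min component was tested with 40-min terms in the model, and the trend with both. A shared period was scanned from 24 to 120 min in steps of 2 min. The 42 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. List peaks were local maxima of the 3-point running mean that were highest within 12 min on each side, and lists whose mean profile had an SD of at least 0.5, a limit set after seeing the profiles, were used for intervals. The named genes were the 12 largest differences in each direction past the threshold in both comparisons, the 8 largest amplitudes, the 10 largest 80-min amplitudes, the 5 largest slopes each way, up to 4 members of each list past the threshold, and 24 genes fixed by name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

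Added after the data were seen were the measured phase of each array as a covariate (the angle of the first 2 principal components of the other random portion of the probe sets, with 2 harmonics), the split at the missing array number, the block of 11 pairs, and periods of 48 and 52 min. Other settings were scalings, a pseudocount of 50, filters, variance models, array name suffix, lags, periods and time points left out. Each test was checked on simulated data made from the real means and spread of 5372 probe sets, with 200 changed. At 0.5 on the log2 scale the level comparison recovered 83.5% of them with 1 false call, and the first 40 min comparison 82.0% with 0. The simulated errors were independent between time points, which real neighbouring samples need not be.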

Results

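Transcript levels were measured on 48 Affymetrix Yeast 2.0 arrays, 1 per time point, from a single continuous culture of Saccharomyces cerevisiae IFO0233, a strain whose respiration and transcription cycle together with a usual period of 40 to 45 min. Samples were taken every 4 min. The first 11 arrays, from 13.8 to 14.5 h after inoculation, were the control, and 37 arrays from 14.6 to 17.0 h followed the addition of phenelzine, a monoamine oxidase inhibitor used as an antidepressant. The hours are as labelled. Those of the control lie before the 16 to 24 h at which the growth protocol says oscillations usually begin, and the last phenelzine samples lie within it. The purpose stated for the series was to lengthen the cycle to double its period. There was no second culture, so time points stand in for replicates, and p-values measure only the spread between time points of this culture. No untreated culture was sampled over the same hours. As deposited, the median log2 signal of the tested probe sets was 10.20 ± 0.19 (SD, n = 11) in control arrays and 10.17 ± 0.24 (SD, n = 37) in phenelzine arrays, and the number of arrays limits the precision.

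Before phenelzine, most of the transcriptome rose and fell once over the control samples. A 40-min rhythm passed the threshold for 3586 of 5372 probe sets (limma F test with Benjamini-Hochberg adjustment). Among the widest swings were those of genes of sulfate uptake and methionine synthesis. MET3, ATP sulfurylase, had an amplitude of 2.69 on the log2 scale (adjusted p = 4.4e-07), and its highest control sample was 42.3-fold above its lowest. The amplitude was 2.88 for OPT1, a peptide and glutathione transporter, 2.72 for MET1, 2.71 for STR3, 2.30 for MET14, 2.21 for MET16, 2.19 for SUL2, a sulfate permease, and 2.77 for the short open reading frame YKL068W-A. Of the sulfur assimilation and methionine list 30 of 31 genes were rhythmic, as were 98 ribosome biogenesis genes, all but 5 of that list, with a median amplitude of 0.60. Cytosolic ribosomal protein genes swung less, with a median amplitude of 0.11 and 87 of 127 past the threshold. Mitosis and cytokinesis genes passed in 5 of 20 cases. The control samples spanned 40 min, so a rhythm could not be told from a single rise and fall.

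**Figure D1:**
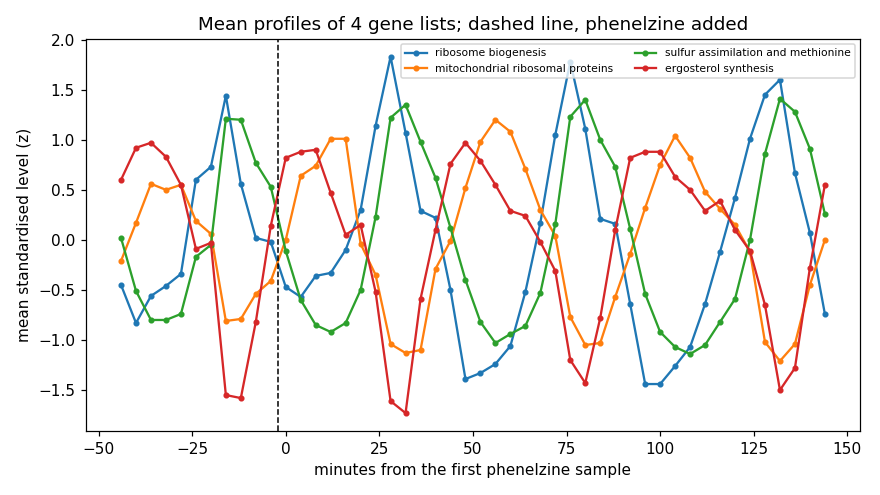
Mean standardised level (z) of 4 gene lists at each of the 48 time points, in minutes from the first phenelzine sample. The dashed line marks the addition. In the 3-point running mean, ribosome biogenesis genes peaked at -20, 28, 76 and 128 min. Mitochondrial ribosomal protein genes peaked in it at -32, 12 and 56 min and 48 min after that. Without the running mean, some of these peaks lie at a neighbouring time point.

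After phenelzine the same groups went on cycling. In the 3-point running mean the last interval between peaks was longer than the first in the 4 lists named next. Without smoothing, both were 48 min for mitochondrial ribosomal protein genes. Ribosome biogenesis genes peaked at -20, 28, 76 and 128 min from the first phenelzine sample. Mitochondrial ribosomal protein genes peaked at -32, 12 and 56 min and 48 min after that. Sulfur assimilation genes peaked at -12, 32, 80 and 136 min, and ergosterol synthesis genes at -36, 4, 48 and 96 min. The first interval of each of these 4 lists ended after the addition. Over the 25 lists with a clear mean profile the median interval was 44 min for the first (28 to 48) and 48 min for the second (20 to 64). It was 50 min for the third (24 to 56), which 22 lists had. The third was 48 min without smoothing, no longer than the second, and 52 min with a 5-point mean. The position of each array in the cycle, read from the first 2 principal components (47.6% and 19.3% of variance), gave a mean cycle of 44.2 min at the start, 47.6 min next and 51.4 min last. The cycles behind the 44.2 min also ended after the addition, so it is not a length from before phenelzine. These lengths have no replicate culture behind them, and peak times are resolved only to the 4-min sampling step.

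A single shared period fitted to the phenelzine arrays explained most variance at 50 min, 58.4% of it. The best period was 46 min over the first 18 of these arrays and 54 min over the last 19. Both optima were shallow. A 50-min period explained 62.1% in the first 18 arrays, against 63.4% at 46 min. In the last 19 it explained 63.7%, against 65.3% at 54 min. With a 40-min period, limma called 0 probe sets after the addition, and 1212 had an unadjusted p under 0.05. With a 44-min period it called 4416. With 48 min, a period chosen after the data were seen, it called 4820, among them every gene of the ribosome biogenesis list and all 31 sulfur genes. The 40-min rhythm itself differed between control and phenelzine for 951 probe sets by an interaction test, including 12 of 14 gluconeogenesis and glyoxylate cycle genes and 28 of 54 genes of other amino acid biosynthesis. That count was 0 with the values as deposited and 70 with columns centred on their median. It was 40 at a period of 44 min, and 265 on the measured phase, 52 of them shared with the 951. Since a 40-min rhythm passed for 0 probe sets after the addition, this test cannot tell a longer period from a change in a gene's own rhythm.

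**Figure D2:**
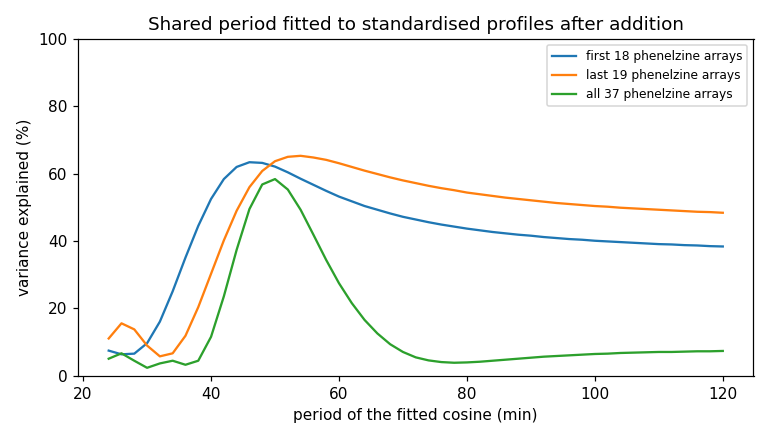
Share of variance (%) explained by 1 cosine of each period (min), shared by all tested probe sets, in the first 18, last 19 and all 37 phenelzine arrays. The highest points lie at 46, 54 and 50 min.

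A component of 80 min, as a doubled period would give, was called for 0 of 5372 probe sets by limma, and 137 had an unadjusted p under 0.05. No gene list had a member past the threshold. Without the first 10 phenelzine time points the same fit called 2377 probe sets. That count cannot tell a doubled period from the ordinary cycle, because the fit held no term near the longer cycle. In the last 19 phenelzine arrays 1 cosine of 80 min explained 54.4% of variance, against 65.3% at 54 min and 30.3% at 40 min. In simulated data carrying the real oscillation, an added 80-min component of 0.5 on the log2 scale was recovered for 91.0% of 200 probe sets. Smaller components were not simulated, so a weaker one could be missed. The median 48-min amplitude over all tested probe sets after the addition was only 0.23. Doubling the longer cycle seen after the addition would also give a period above 80 min. With a period of 88 min the fit called 0 probe sets, and 181 had an unadjusted p under 0.05. Periods above 88 min were not tested in this fit.

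Averaged over time points, 3 genes of the glycine cleavage system, GCV1, GCV2 and GCV3, and a drug efflux pump stood higher after phenelzine. GCV1 was 1.68-fold higher, 12.36 ± 0.53 (SD, n = 37) against 11.62 ± 0.20 (SD, n = 11) on the log2 scale, with limma's adjusted p = 0.021. GCV2 was 1.43-fold and GCV3 1.17-fold higher. With the measured phase and linear time as covariates, a fit added after the data were seen, these differences reversed to -0.34 for GCV1, -0.14 for GCV2 and -0.11 for GCV3 on the log2 scale. PDR5, a multidrug transporter, was 1.52-fold higher (SE 0.10 on the log2 scale, adjusted p = 0.00034), as was YLR460C. RNR3, a ribonucleotide reductase subunit, fell by 0.39 on the log2 scale (SE 0.09, adjusted p = 0.029), and GRX4, a glutaredoxin, fell by 0.25. In all 25 of 5372 probe sets passed the threshold, 19 higher and 6 lower. Among the other genes that passed and were named for the largest differences, log2 differences above 0 ran from 0.24 for PRP46 to 0.43 for YAR066W. YAR068W, KAR1, DSF1, UFO1 and TIM50 lay between them. Those below 0 ran from -0.15 for MSB2 to -0.27 for IRC19, with SLD5 and LCB4 between them. Only 1 probe set passed with the values as deposited, and 0 passed with consecutive windows of time points as a random block. Setting only the first 11 phenelzine samples against their control partners 44 min earlier, also added after the data were seen, 454 passed, 215 higher and 239 lower. GCV1 at 0.14, PDR5 at 0.28 and RNR3 at -0.49 kept their calls in it. GCV2 at 0.14, GCV3 at 0.04, YAR066W at 0.10, DSF1 at 0.08, TIM50 at 0.16 and PRP46 at 0.07 did not pass. Neither did IRC19 at -0.17, SLD5 at -0.15, LCB4 at -0.11 and MSB2 at -0.11. Random exchanges within pairs were run only for pairs 40 min apart, where they gave up to 363 calls. Chance is thus not excluded for the 454.

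Array numbers in the labels skip 91, and only phenelzine samples lie after it. The 3 prime over 5 prime ratio of the spiked dap control was 1.59 ± 0.13 (SD, n = 32) on the log2 scale on arrays before the missing number and 2.40 ± 0.23 (SD, n = 16) on those after it. Among the 32 arrays before it, a split chosen after the data were seen, 0 probe sets passed the level comparison, and 344 had an unadjusted p under 0.05. There the log2 difference was 0.39 for GCV1 (adjusted p = 0.42), 0.46 for PDR5 (adjusted p = 0.052) and -0.45 for RNR3 (adjusted p = 0.052). All 7 arrays of name suffix 02 were phenelzine samples too.

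Of 42 gene lists, 9 passed limma's camera test with a preset correlation in the level comparison, and 0 passed with an estimated correlation. The multidrug resistance list stood higher (adjusted p = 1.9e-05, and adjusted p = 0.46 with an estimated correlation). Of its 19 members 1 was higher past the threshold over all genes and 6 were when adjusted over the list alone, PDR5 among them. Hexose transporters had a median log2 difference of 0.24, with HXT2 at 0.38 and HXT3 at 0.37, and no member passed (adjusted p = 0.02, and adjusted p = 0.96 with an estimated correlation). The iron regulon list, with ENB1 called at 0.19, had adjusted p = 0.69 with an estimated correlation. For the low-oxygen list it was adjusted p = 0.61, with 0 of 25 members called, and for cell wall proteins, with CCW14 called at 0.13, adjusted p = 0.42. Lists that stood lower were cytosolic ribosomal proteins, tRNA synthetases, other amino acid biosynthesis and DNA replication, each with adjusted p = 0.96 with an estimated correlation. RNR3 was the 1 member of these that passed. Of 24 genes fixed by name 23 had no call, with log2 differences from -0.33 for MET16 to 0.45 for GRE2. Among them were FMS1, a polyamine oxidase, at -0.07, SNQ2 at 0.15, TPO1 at 0.23, FLR1 at 0.14, HSP12 at 0.19 and ACT1 at 0.00.

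In the first 40 min after the addition, set against samples 40 min earlier, few genes passed the threshold. That lag was shorter than the mean first cycle of 44.2 min, so the members of a pair were not quite at the same phase. RNR3 fell by 0.47 on the log2 scale (SE 0.05, adjusted p = 0.0024, limma, 10 pairs). YER138W-A rose by 0.66 (adjusted p = 0.0033), ATP19, an ATP synthase subunit, by 0.30 (adjusted p = 0.04) and RPL27A, a ribosomal protein, by 0.15 (adjusted p = 0.021). These were the 4 calls of 5372 probe sets. With a lag of 44 min 456 passed, with 36 min 0 passed, and with the values as deposited, which move the median of all tested probe sets by -0.16, 0 passed. The count at 44 min was not set against random exchanges within pairs.

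In this comparison 7 lists passed camera with a preset correlation, and each had adjusted p = 0.88 with an estimated correlation. Ribosome biogenesis genes had a median of 0.11, with 89 members higher, 0 of them past the threshold, and NOP53 at 0.35. The median was -0.22 for gluconeogenesis and glyoxylate cycle genes, with PCK1 at -0.73 (adjusted p = 0.26), and -0.12 for glycogen and trehalose genes, with TSL1 at -0.36. Cytosolic ribosomal proteins and translation factors had medians of 0.01 and 0.02 (-0.01 and 0.01 median centred), and other amino acid biosynthesis and autophagy genes -0.06 and -0.09.

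During the hours after the addition GCV1 rose by 0.69 per hour on the log2 scale (SE 0.04, adjusted p = 1.3e-14). The amino acid permease genes GNP1 and BAP3 rose by 0.77 and 0.72 per hour, and YHL008C and YJL043W by 0.76 and 0.81. The short reading frames YMR030W-A and YLR264C-A fell by 1.26 and 0.91 per hour, AQY1, an aquaporin, by 0.86, YIL060W by 0.76 and YAR035C-A by 0.75. A linear trend passed for 582 probe sets in limma's test, 235 rising and 347 falling. As deposited, where the median slope of all tested probe sets was 0.12 per hour, 805 rose and 12 fell. These hours span the missing array number, and with the measured phase, a fit added after the data were seen, 2553 probe sets had a trend over all phenelzine arrays and 658 over those before that number. Drug and drift over time cannot be separated in this design.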

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

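The tests of the missing array number, the matched phase and normalization were chosen after the result was seen, while the random splits, the runs of consecutive arrays, the component of 2 cycles and the exchanges within pairs had their predictions written first. The 40-min rhythm differed between control and phenelzine for 951 probe sets, which an interaction test picked out. That test cannot tell a longer period from a change in a gene's own rhythm. Of 100 random splits of the 48 arrays 1, the real one, gave as many, and the highest other gave 32, so a random split is excluded, though not one of neighbouring samples. The 4 calls of the first 40 min are another matter: 5 of 100 exchanges within pairs, the real one among them, gave as many, and the highest other gave 363, so chance is not excluded for them. The spiked dap control, outside the main measurement, had a 3 prime over 5 prime ratio 0.81 higher on the log2 scale after the missing array number than before it (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). Fission yeast probe sets, also outside it, reached a median log2 of 3.13 as deposited on 1 phenelzine array, against at most 2.32 on control arrays. That array also had the highest median intensity of all probe sets, 86.8. The mean of this median log2 was 1.94 ± 0.35 (SD, n = 37) on phenelzine and 1.69 ± 0.33 (SD, n = 11) on control arrays.

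Cycles were longer late in the series than at its start, 51.4 min against 44.2 min. A wrong interval at the missing array number is argued against, since the phase advance there was 1.18 times the mean of the other steps, where under 0.5 was needed. Between-array normalization is argued against too, as the last cycle was 51.4 min with median-centred columns. The cycles behind the 51.4 min all ended on arrays after the missing number. Whether the labelling difference there bears on their length was not tested. Drift of the culture without the drug cannot be told apart from phenelzine, because the control samples held 0 complete cycles. An effect of phenelzine may account for the longer cycles and stays open as untested.

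At a matched phase 589 probe sets differed between phenelzine and control time points, and 1 of 100 random splits, the real one, gave as many, with 3 the highest other. Runs of 11 consecutive arrays give another picture: 18 of the other 37 runs gave as many, up to 2165. In the level comparison without phase 17 of 37 did, up to 804 against 25. Steady drift over the hours may thus produce counts of this size. The runs cannot tell it from other causes, however. The run with 2165 started at 96 min, wholly after the missing array number, where phenelzine had also acted longest. Runs starting from 44 to 60 min gave 0 at a matched phase. In the level comparison 1 of 100 random splits gave 25 and the highest other gave 4, but random splits break up neighbouring samples. By design, the labelling difference at the missing array number cannot account for the 153 probe sets called among arrays before it. That count was above the other random splits of those arrays, of which the highest gave 125. Such splits also break up neighbouring samples, and runs of consecutive arrays were not tried among those arrays alone. Of the 471 called only over all arrays 50 stayed called, with the same sign, with later arrays as a covariate. For the other 421 the labelling difference cannot be told apart from the treatment, as no control array lies after the missing number. An effect of phenelzine stays open for both.

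Alternate cycles that differ, as a doubled period would give, were looked for as a component of 2 measured cycles, which 12 probe sets had. Components of other lengths gave more, up to 107, against the prediction for a doubled period. No technical explanation was tested for this pattern, and phenelzine arrays cover only about 3 cycles.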

How the results depend on the processing

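The fits with the measured phase, the split at the missing array number, the block of pairs 44 min apart and periods of 48 and 52 min were chosen after the data were seen. The 40-min rhythm before addition stayed between 2909 and 3729 probe sets under every setting run, and between 3289 and 3568 without each control time point in turn. The 25 calls of the level comparison became 1 as deposited, 13 median centred, 45 with the array suffix as a covariate, 147 without the first 10 phenelzine time points, and 1, 5, 325 and 358 for the 4 successive windows against control. They became 0 with windows as a random block, 0 for arrays before the missing number, 589 with the measured phase, 153 with it before the missing number, 218 with it and a covariate for later arrays, and 932 with it and linear time, a set that shares 90 calls with the 589, 76 of them with the same sign. With the replicate block of pairs 44 min apart, which also limits the contrast to the first 11 phenelzine arrays, they became 454, nearly the lag of 44 min. Against 4 calls, the first 40 min gave 0 as deposited, 2 median centred (1 up and 1 down, against 3 and 1), 10 without the variance trend, 0 and 456 at lags of 36 and 44 min, 0 without the pair term, 295 with the measured phase, and 2 to 8 without each pair in turn. The 951 rhythm differences became 0 as deposited, 70 median centred, 571 without suffix 02, 0 and 40 at 36 and 44 min, 954 at 48 min, and 265 on the measured phase. For the rhythm after addition, 0 became 4416 at 44 min, 4820 at 48 and 4804 at 52. For the 80-min component, the count stayed 0 at 88 min. It became 1 at 72 min, 12 for 2 measured cycles and 2377 without the first 10 time points. The trend count of 582 became 2553 with the measured phase, and its split of 235 up and 347 down became 134 and 339 median centred. The best period, 50 min, was 46 in the first 18 arrays and 54 in the last 19, both with shallow optima. The third interval between list peaks, 50 min, was 48 without smoothing, as the second was, and 52 with a 5-point mean. The 9 lists of the level comparison became 0 with an estimated correlation and 0 with fry, and their split of 5 up and 4 down became 4 and 2 median centred. The 7 of the first 40 min, 3 up and 4 down, became 0, 0, 14 as deposited (3 and 11), 8 median centred (1 and 7), and 2 and 11 at lags of 36 and 44 min.

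With the measured phase and linear time, the log2 difference turned to -0.34 for GCV1, -0.14 for GCV2, -0.11 for GCV3, -0.11 for YAR066W, 0.00 for YAR068W, -0.08 for DSF1, -0.06 for PRP46 and 0.05 for LCB4, and, among genes without a call, to -0.19 for HSP26, -0.56 for CTT1, -0.09 for SNZ1 and 0.11 for PDX3. RPL27A turned to -0.01 in the first 40 min as deposited, where the median of all tested probe sets was -0.16 as well, a shift shared by all genes. Of 786 values of the 40 named results that had passed, 606 kept direction and call, 171 lost the call and 9 reversed. The 606 include 168 amplitudes from before the addition, which do not concern phenelzine and lost 0 calls. Of the 171 losses 129 were in the level comparison, 29 in the first 40 min and 13 among the slopes. Fewer arrays enter some of these fits; otherwise the cause was not tested. With the replicate block CTT1 turned to -0.45. The order of time points makes these pairs, not the labels, and 10 of 11 control samples correlated best with their own partner. Signal over background limits dim probe sets, of which 126 were left out.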

Other observations

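All tests in this part were chosen after the data were seen, although the prediction on one-carbon genes was written before their values were. With the measured phase as a covariate, 10 of 19 multidrug resistance genes were called higher and 0 lower, against 2 higher and 0 lower among arrays before the missing number. The 10 included RSB1, a sphingoid base transporter, at 0.60 (SE 0.11, limma's adjusted p = 0.00052), PDR15 at 0.33 and YOR1 at 0.31. The copper transporter gene CTR3 stood 0.54 higher. PCK1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was at -0.66 on the log2 scale (adjusted p = 3.2e-05), and 5 of 14 genes of its list were called lower (2 among arrays before the missing number), ACS1 at -0.26 and ICL1 at -0.23 among them. RNR1 at -0.21, RNR2 at -0.14 and POL30 at -0.19 were called lower beside RNR3 at -0.42. The list tests had adjusted p = 0.29 with an estimated correlation for all 3 of these lists, and runs of consecutive arrays gave counts as large as the control run.

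Among arrays before the missing number, the log2 difference at a matched phase was 0.46 for PDR5 (adjusted p = 0.0017), 0.40 for GCV1 (adjusted p = 0.025), -0.68 for PCK1 (adjusted p = 0.0026) and -0.51 for RNR3 (adjusted p = 1.7e-07). With linear time as a further covariate over all arrays the difference was -0.56 for PCK1 (adjusted p = 0.0079), -0.63 for RNR3 (adjusted p = 2e-08), -0.34 for GCV1 and 0.10 for PDR5 (adjusted p = 0.32), so for GCV1 and PDR5 a step at the addition was not separated from a gradual rise.

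The rise of GCV1, GCV2 and GCV3 led to the hypothesis that other one-carbon genes rose with them. Of 19 such genes 4 were called higher at a matched phase and 2 lower, short of the majority that the prediction had set. Over all 5372 probe sets 285 were called higher and 304 lower, smaller shares than among the 19. Whether the one-carbon genes exceeded those shares by more than chance was not tested. SHM2, a serine hydroxymethyltransferase, was at 0.31, ADE17 at 0.29, FOL1 at 0.18 and MET12 at 0.10, while SHM1 was at -0.08 and MET7 at -0.16. LPD1, counted among the 19 and also a subunit of the glycine cleavage complex, was at 0.02 (adjusted p = 0.31).

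The cycle did not lengthen evenly. From one point to the opposite point of the plane of the first 2 principal components took between 20.7 and 24.1 min in 6 successive stretches and 30.5 min in the last.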
